A study of Mus musculus with 6 samples.

How the data were processed

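Poly-A RNA was sequenced from retinal ganglion cells (RGCs, the neurons whose axons form the optic nerve) of mice. The 6 libraries fall into 3 groups of 2. Adult control RGCs carried an AAV2 vector with mCherry and a scrambled shRNA mimic. Adult miR-1247 RGCs carried the same kind of vector with a mimic of the microRNA miR-1247-5p. The third group is RGCs of embryonic day 18 (E18), which received no vector. Per the labels' protocols, each adult condition pooled about 5000 cells of 10 retinas, purified on Thy1 antibody and sorted for mCherry. About 50000 E18 cells were purified on Thy1 antibody and not sorted. Age, vector, sorting and number of cells therefore cannot be separated between E18 and adult libraries. The same protocols give an RNA integrity number of at least 9, a TruSeq poly-A library kit and paired reads of 100 bases. The labels do not say whether the 2 libraries of a group come from separate animals. Every p-value of a single locus is therefore set against the spread between these libraries, which may be technical. P-values of gene lists and of seed matches compare loci with other loci and do not measure how well a result repeats between libraries.

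The authors mapped reads to the mm39 genome with HISAT2 and computed FPKM (fragments normalized for transcript length and for the number of mapped reads) with Cufflinks and Cuffdiff, per the submitters' processing notes, which give no versions. The deposited FPKM table holds 1 column per library. It has 11104 entries for 10361 gene names and 10889 assembled loci. In the deposited FPKM values 1e-05 had been added to every entry, and this was taken off again. Many genes of other retinal cell types have no entry, and the filter behind this is not stated. The authors also deposited log2 ratios of the group means, miR-1247 over control and control over E18. All 11104 entries in both columns were within 0.003 of the ratios recomputed from the FPKM values. These log2 columns were used for that check only. Counts of reads are not part of the table, so the depth of each library is unknown, no counting interval can be given, and the authors' own test was not repeated.

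Entries of 1 locus with different gene names hold the same values and were taken once, a choice made after seeing the table. A name such as Fdps/Rusc1 stands for a locus that holds both genes. Conversely, 668 gene names have more than 1 locus, and for 661 of them all loci have the same coordinates. Values can be divided between such loci differently in different groups. Every fold change of such a gene was therefore also computed on the sum of its loci. An exact 0 may be a failed estimate and not an absent transcript. Of the tested loci, 321 (3.11%) were at 0 in at least 1 library and 114 in both libraries of a group. For loci listed at 0 in a group the values are given without a fold change. The kit as named does not keep the strand, so loci on opposite strands at the same coordinates may share reads.

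The comparisons, gene lists, thresholds and the rule for naming genes were written before the data were examined. Loci with a mean of at least 1 FPKM over the 6 libraries were tested, 10320 in all. All 6 libraries entered 1 linear model of log2(FPKM + 1) with 3 group means in limma 3.58.1 under R 4.3.3, with moderated variances that follow the mean level. P-values were adjusted over all tested loci (Benjamini-Hochberg) and called at 0.05. All tests are two-sided. Fold changes are differences of mean log2(FPKM + 1), which understate changes of weakly expressed genes, and are given as log2 fold change ± standard error. Levels are group means in FPKM ± SD, with n = 2 libraries in each group throughout. Tables were handled with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9.

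Gene lists were tested with camera, which compares a list with all other loci, at a preset correlation between genes of 0.01, and again with the correlation estimated from the data. Lists needed at least 5 tested members, which 18 of the 32 met. The 19 gene lists were RGC identity, nuclear-encoded oxidative phosphorylation, the mitochondrial genome, the mitochondrial ribosome, mitochondrial fusion, fission and transport, the primary cilium, the motile cilium, axon growth and growth cone, axon guidance, synaptic vesicle and release, voltage-gated channels of mature neurons, glutamate, GABA and glycine receptors, cell cycle, injury and integrated stress response, interferon response and antigen presentation, immediate early and dissociation response, cholesterol biosynthesis, cytoplasmic ribosomal proteins, and the Dlk1-Dio3 imprinted locus, which holds Mir1247. The 13 marker lists were rods, cones, bipolar cells, amacrine cells, Müller glia and astrocytes, microglia and macrophages, endothelial cells and pericytes, erythroid cells, pigment epithelium, retinal progenitors, fibroblasts, oligodendrocytes and lens crystallins.

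Genes were named by rule. For each contrast the rule takes the 10 highest and 10 lowest log2 fold changes among called genes with at least 5 FPKM in the higher group and no overlap between the replicates. It adds up to 4 members of each list with the smallest p. Genes always included were Mir1247, Dio3os, Dio3, Thy1, Rbpms, Slc17a6, Pou4f1, Pou4f2 and Gap43, among others. Not every gene that the rule picks is named in the text. Members of list counts of 5 or fewer, and the few genes said to be so, were named after their values were seen.

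The relation between the developmental contrast (E18 minus control) and the miR-1247 contrast was measured across loci by Pearson's r, Spearman's rho and the covariance. Both contrasts subtract the same control libraries, which alone gives a positive value. For comparison, 100 data sets were simulated in which the miR-1247 group was unchanged, and 100 in which all groups were. Their noise follows the spread between libraries of a group, so a deviation common to both control libraries is left out. Genes are not independent replicates, so no p-value is given. Targets of miR-1247-5p were sought as 7-base matches to its seed (GGACGGG, or GACGGGA) in annotated 3' UTRs of GENCODE vM39 on GRCm39, the assembly also called mm39. Of the 10361 names, 10196 matched by symbol and 2 by an older symbol, and 9969 had a 3' UTR. The mature sequence ACCCGUCCCGUUCGUCCCCGGA was found in the annotated Mir1247 hairpin on chromosome 12, 110244482 to 110244563, minus strand. Random lists (10000) matched on UTR length and level served as description.

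The tests were checked on simulated data with 200 of the 10320 loci changed. For the developmental contrast 26%, 64%, 98% and 98% of loci with a log2 change of 0.5, 1, 2 and 3 were recovered, with 15 false calls. For the miR-1247 contrast the shares were 26%, 72%, 94% and 100%, with 11 false calls. A simulated list lowered by 0.5 was recovered and no other list was called. Seed-match loci lowered by 0.2 in a simulation were also recovered (difference of medians −0.194). Noise in these simulations was drawn independently for each locus. False list calls that arise from correlation between genes were therefore not probed.

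Alternatives fixed in advance were a pseudocount of 0.1, no level filter, a minimum of 5 FPKM, median ratio scaling, quantile normalization, scaling to equal totals (TPM), replicate number as a block, no variance trend, only the 4 libraries of a contrast, each library left out in turn, 1 control library for each contrast, rank correlation, an unadjusted threshold, an estimated correlation for lists and 8-base seed matches. Alternatives added after seeing the data were leaving out loci at 0 in any library, summing the loci of a gene name, and leaving out mitochondrial loci with the rest rescaled.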

Results

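The table gives gene expression in FPKM for 6 mouse RGC libraries: 2 of adult control RGCs, 2 of adult RGCs with the miR-1247-5p vector and 2 of E18 RGCs. Totals of the listed FPKM values ran from 339224 to 392238 per library. Libraries of a group were alike across loci (r of log2 values 0.976 to 0.979). Control and miR-1247 libraries correlated at 0.951 to 0.955, and E18 with adult libraries at 0.678 to 0.685. The introduced microRNA could not be checked, because Mir1247 has no entry in the poly-A table, and neither have Dio3 and Dio3os. They were not analysed here.

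The first comparison asks how RGCs differ between E18 and the adult. The lists of axon growth, ribosomal proteins and cholesterol synthesis were higher in E18, and those of synaptic, ion channel and receptor genes lower. With an estimated correlation the ribosomal list alone kept its call, and the others had an adjusted p from 0.0520 to 0.137. Gap43, a growth cone protein (chromosome 16, 42068805 to 42161014 in mm39), was at 148 ± 10.0 FPKM in adult control and 1326 ± 12.1 FPKM in E18 RGCs. Tubb2b, a tubulin of developing neurons, rose from 34.6 ± 1.48 to 1815 ± 4.51 FPKM. Snap25, which drives fusion of synaptic vesicles, fell from 1747 ± 28.3 to 169.5 ± 9.14 FPKM at 1 locus. The sum of its 2 loci fell from 3022 ± 11.6 to 569.8 ± 17.7 FPKM. Of 10320 loci tested, 4045 were higher in E18 and 3063 lower, 2076 and 1550 of them at least 2-fold. The excess of higher loci rests on the scaling, with 3442 higher and 3517 lower under median ratio scaling and 3548 and 3440 without mitochondrial loci. The median locus was higher in E18 by 0.15 (log2), and by 0.01 under median ratio scaling.

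Among the genes with the highest fold changes in E18, Nnat, an imprinted gene of the developing brain, rose from 19.0 ± 1.52 to 1240.0 ± 5.03 FPKM (log2 fold change 5.96 ± 0.0732). Gpc2, a neuronal glypican, rose by 5.84 ± 0.184, and the ribosomal protein genes Rpl34 and Rpl29 by 5.98 ± 0.574 and 5.79 ± 0.167. Tardbp, Dctn3 and Ccl27a were listed at 0 in all 4 adult libraries, against 95.5 ± 9.96, 71.2 ± 3.81 and 55.9 ± 1.85 FPKM in E18. Dctn3 and Ccl27a have the same locus coordinates (chromosome 4, 41646764 to 41774247). The mitochondrial genes mt-Cytb and mt-Nd6 were listed at 0 in both control libraries only. Dcx and Cd24a, which are expressed by young neurons, enter the rule when loci of a name are summed, and rose by 5.74 ± 0.117 and 5.66 ± 0.104.

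Among the genes with the lowest fold changes, Mgarp, a mitochondrial transport protein, fell from 1153 ± 12.4 to 10.5 ± 2.42 FPKM (−6.67 ± 0.131). Rd3l (log2 fold change −6.95), Rasgrf1 (−6.54), Fgf1 (−6.14), Faim2 (−5.80) and Sparcl1 (−5.77) fell as well. Single loci of App, Slc6a11, Sv2a and Gabbr2 also stood among the lowest, but each name has more than 1 locus at the same place. The App locus was at 143 ± 10.5 FPKM in control and at 0 in both E18 libraries, whereas the sum of its loci fell by 0.35. The sums for Slc6a11, Sv2a and Gabbr2 changed by −2.30, −2.23 and −1.70.

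Of 36 tested axon growth genes, 30 rose and 3 fell in E18, with the same counts when adjusted over the list alone. Besides Gap43 and Tubb2b, Dpysl3 rose by 4.56 ± 0.0619 and Stmn1 from 506 ± 0.408 to 2020.3 ± 19.8 FPKM. The 3 that fell were Klf9, a transcription factor that restrains axon growth, Cntn1 and Dpysl2. The list's median was 1.80, adjusted p = 1e-08, and adjusted p = 0.103 with an estimated correlation. Of 80 cytoplasmic ribosomal protein genes 76 rose and 1 fell (Rps2). The counts were 77 and 1 when adjusted over the list alone. Rplp0 rose from 32.4 ± 2.21 to 420.3 ± 4.30 FPKM and Rps3 from 73.4 ± 4.55 to 408 ± 9.05 FPKM. The list's median was 1.85 (adjusted p = 4.19e-15), and its call held with an estimated correlation (adjusted p = 0.0292). It was the only developmental list call that did.

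All 22 genes of cholesterol synthesis and its control changed, 19 up and 3 down, the same when adjusted over the list alone. Hmgcs1, at the entry to the pathway, rose by 2.23 ± 0.0504, Cyp51 by 2.24 ± 0.0897 and the Fdps/Rusc1 locus by 1.22 ± 0.0478. Insig1, which acts in control of the pathway, was among those that fell. The list's mean was 0.99 (adjusted p = 0.000362, and adjusted p = 0.103 with an estimated correlation).

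Of 32 synaptic vesicle genes 25 fell and 6 rose in E18. Vamp2 (−2.18), Nsf (−2.77), Syp (−2.23) and Snap25 (−3.36, and −2.41 over its 2 loci) were among those that fell. The list's median was −1.65 (adjusted p = 7.71e-08, and adjusted p = 0.0520 with an estimated correlation). Of 35 channel genes of mature neurons 25 fell and 4 rose (Scn3a, Scn3b, Hcn4 and Cacna1b). Kcnj9 (−4.80), Scn2b (−3.61) and Kcnc1 (−2.62, and −2.22 over both loci) fell. Their median was −1.60 (adjusted p = 5.01e-07, and adjusted p = 0.0520 with an estimated correlation). Of 30 receptor genes 21 fell and 4 rose (Gria2, Grik2, Gabra5 and Gabbr1). Glrb (−3.83) and Grm7 (−1.93) fell, and the median was −0.92 (adjusted p = 3.23e-05, and adjusted p = 0.137 with an estimated correlation). For these 3 lists the counts adjusted over the list alone were the same.

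RGC identity genes went both ways at E18. Of 22, 14 rose and 7 fell, also when adjusted over the list alone (adjusted p = 0.198 for the list). The transcription factors Pou4f1 and Pou4f2 rose by 1.80 ± 0.0535 and 1.08 ± 0.0738, the RNA binding protein Rbpms by 1.45 ± 0.0972 and the neuronal tubulin Tubb3 by 2.36 ± 0.0375. The glutamate transporter Slc17a6 fell from 122 ± 3.57 to 52.6 ± 3.03 FPKM, the surface protein Thy1 from 855 ± 11.4 to 352 ± 8.46 FPKM and the heavy neurofilament Nefh from 84.0 ± 2.43 to 4.80 ± 0.281 FPKM. Markers of other cells differed as well. The amacrine genes fell, among them Gad2 from 81.8 ± 0.907 to 0.856 ± 0.246 FPKM, Slc6a9, and Npy, which was at 0 in 1 E18 library. Both rod genes (Rom1 and Reep6) fell, as did 2 of 3 bipolar genes (Prkca and Car8) and Mbp of oligodendrocytes. Of 5 Müller glia and astrocyte genes Aldoc, Dkk3, Apoe and Glul fell and Vim rose. That list had adjusted p = 0.0510 and passed 0.05 under 6 alternatives, among them a pseudocount of 0.1 (0.0458), without control library 1 (0.0448) and without control library 2 (0.0184). The progenitor genes Dapl1, listed at 0 in all adult libraries, and Hes6 rose, as did Col6a1 of fibroblasts. The lens gene Crybb3 (log2 fold change −0.58) did not pass. Cone, endothelial, erythroid and pigment epithelium lists had no tested member.

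The other lists did not pass as lists. Axon guidance had 19 up and 12 down of 35 (adjusted p = 0.571), with Plxna3 up (3.49 ± 0.166) and Unc5d (−3.12) and Efnb2 (−1.65) down. Nuclear-encoded oxidative phosphorylation had 21 up and 27 down of 75 (adjusted p = 0.214), for example Atp5e up (1.86) and Sdha down (−1.29). The mitochondrial ribosome had 21 up and 21 down of 78, or 16 and 12 when adjusted over the list alone (adjusted p = 0.744), with Mrpl9 up and Mrpl10 down. Mitochondrial fusion, fission and transport had 6 up and 12 down of 26 (adjusted p = 0.105), with Mfn1 up (2.50) and Pink1 down (−2.21). The primary cilium had 19 up and 11 down of 53, or 19 and 9 when adjusted over the list alone (adjusted p = 0.447), Ift88 up and Ift80 down. The motile cilium had 5 up (Ccdc39, Ccdc40, Spag6l, Cfap69 and Rsph9, listed at 0 in control) and Dnal1 down of 9 (adjusted p = 0.372). Cell cycle had Mcm6, Mcm7 and Rrm1 up and Ccne2 down of 6 (adjusted p = 0.570). Injury and stress response had 11 up and 8 down of 23 (adjusted p = 0.960), with Hspb1 (−3.13) and Vgf (−2.15) among those down. Interferon response had Stat2 and Irf9/Rnf31 up and 4 down of 7, among them H2-D1, Tapbp/Zbtb22 and Ifi27 (adjusted p = 0.273).

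Immediate early genes had 5 up (Jun by 1.70, Klf6, Hspa8, Fos and Dusp1) and 7 down of 16, among them Junb (−1.73, list adjusted p = 0.381). Of the Dlk1-Dio3 locus Meg3 rose from 49.2 ± 1.58 to 502 ± 0.605 FPKM and Begain by 1.76, 2 of 4 tested genes. The counts adjusted over the list alone were the same for every list where no other count is given. Of the named calls of this contrast, 108 of 122 held without each of the 6 libraries in turn. Among those that did not were Ccdc40, Dusp1, Fos, Glul, Hes6, Ifi27, Insig1, Klf6, mt-Nd1/mt-Nd2, Rps2, Rrm1, Scn3a and Stat2. Fos, Dusp1 and Rrm1 also lost their calls under all 3 other scalings, and Hspa8 under median ratio scaling, equal totals, no variance trend and without mitochondrial loci.

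The comparison of adult miR-1247 with adult control RGCs asks what differed with the miR-1247 mimic in place of the scrambled one. Genes that mark RGCs were lower in the miR-1247 libraries. The neurofilament genes Nefl and Nefm (both within chromosome 14, 68320039 to 68362306) fell from 623 ± 5.72 to 310.2 ± 1.14 FPKM (adjusted p = 0.000107) and from 342 ± 5.73 to 152 ± 5.40 FPKM (adjusted p = 0.000211). Nrn1, a neurite growth factor, fell from 286 ± 10.9 to 123 ± 3.12 FPKM. Slc17a6 (chromosome 7, 51271754 to 51320874) fell from 122 ± 3.57 to 54.4 ± 0.637 FPKM. Rbpms fell from 106 ± 6.73 to 53.3 ± 7.26 FPKM, Pou4f1 (−0.80) and Pou4f2 (−0.89) fell, and Thy1 fell from 855 ± 11.4 to 630.4 ± 17.3 FPKM. Gap43 did not pass the test (148 ± 10.0 and 134 ± 10.3 FPKM, adjusted p = 0.238).

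**Figure D1:**
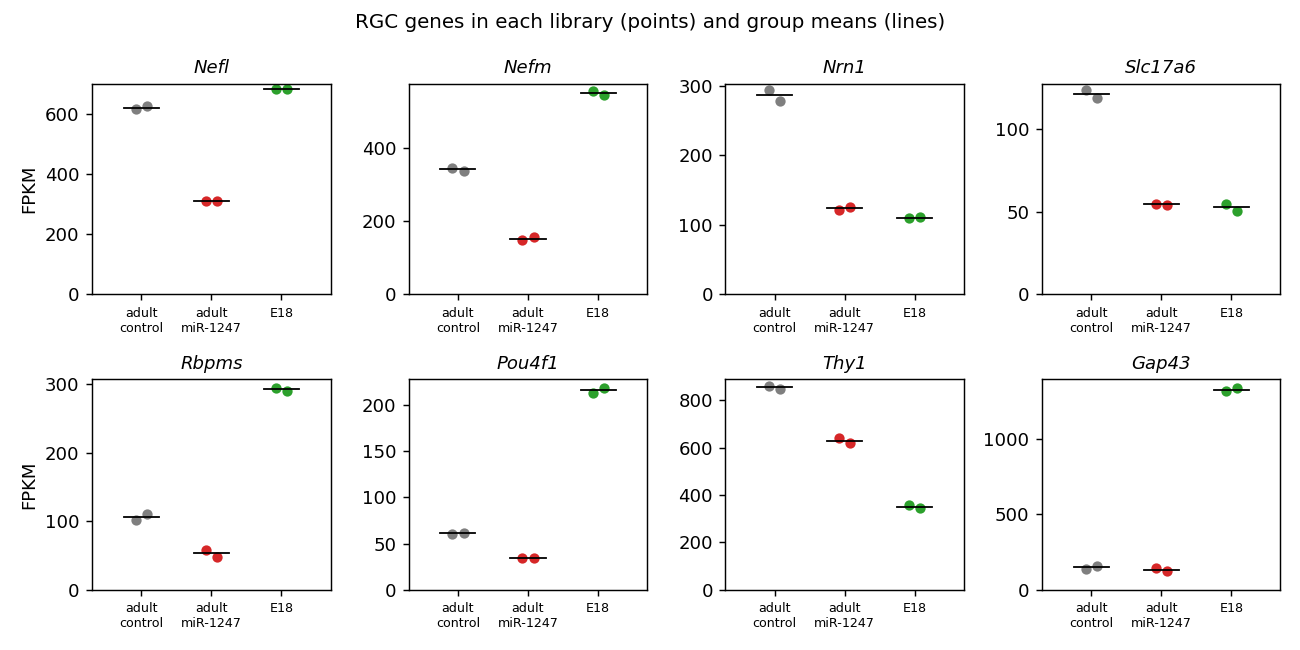
FPKM of 8 genes in each of the 6 libraries (points) with group means (lines), on axes of different range. Nefl, Nefm, Nrn1, Slc17a6, Rbpms, Pou4f1 and Thy1 were lower in both miR-1247 libraries than in both control libraries, while at E18 Rbpms, Pou4f1, Nefl, Nefm and Gap43 lay above adult control.

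In all, 324 loci rose and 571 fell, 56 and 80 of them at least 2-fold. This count rests on every library. It was 116 without control library 1, 83 without control library 2, 63 without miR-1247 library 1, 72 without miR-1247 library 2, and 223 and 221 without E18 library 1 or 2. It was 291 with no variance trend and 295 with only the 4 adult libraries. The size of the split rests on the scaling as well, with more loci down than up under each. Rising loci were 36.2% of calls as deposited, 46.5% (400 up, 460 down) under median ratio scaling and 15.4% (125 up, 685 down) with equal totals. The median locus moved by −0.03 as deposited and by −0.12 with equal totals.

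Of 96 named calls of this contrast, 22 held without each of the 6 libraries in turn. Those were Nefl, Nefm, Nrn1, Slc17a6, Thy1, Pou4f1, Pou4f2, Tubb3, Isl2, Map1b, Ina, Miat, Fdps/Rusc1, Arf6, Miip, Chrna6, Rgs4, Igfbp2, Igfbp4, mt-Cytb, mt-Nd6 and the locus of 9 mitochondrial genes. Of these Thy1 lost its call with no variance trend, Arf6 with its loci summed and the mitochondrial locus of 9 genes under quantile normalization. Rbpms held in 5 of 6. The other calls named in this comparison were lost without at least 1 library.

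RGC identity was the list with the smallest p. Of 22 members 17 fell and none rose, 20 and 0 when adjusted over the list alone. All 22 fold changes were below 0, with median −0.72 (adjusted p = 7.25e-19). It was the only list call of this contrast that held with an estimated correlation (adjusted p = 0.0369), and it held under every other alternative. Opn4, the melanopsin of light-sensing RGCs, fell by 1.55. Of the 17 that fell, 5 were also lower at E18 than in adult control and 12 were higher at E18, such as Pou4f1 (216 ± 3.95 FPKM at E18). The 5 were Thy1, Slc17a6, Nefh, Nrn1 and Opn4, listed here after their values were seen. Other cell types moved beside them. Of the amacrine genes Gad2 (0.38), Npy (0.70) and Slc6a9 (0.29) did not pass. The rod gene Rom1 fell (−0.98) and Reep6 (−0.48) did not pass, while both fell when adjusted over the list alone. Of 5 Müller and astrocyte genes Dkk3 rose by 0.35 and Glul varied too much to pass (293 ± 242 and 714 ± 116 FPKM). That list had adjusted p = 0.0726, 0.0106 without control library 1 and 0.0334 without miR-1247 library 1. Mbp of oligodendrocytes rose by 0.62 and Col6a1 of fibroblasts by 0.97. Of the bipolar genes Prkca (0.47), Car8 and Gng13 none passed, and Prkca did when adjusted over the list alone. Neither of the progenitor genes Dapl1 and Hes6 passed, nor did the lens gene Crybb3 (1.88), which passed only when adjusted over the list alone.

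Other neuronal lists shifted by less. Of 36 axon growth genes 9 fell and 2 rose (Marcks and Marcksl1), 12 and 4 when adjusted over the list alone. Ina (−0.66), Tubb3 (−0.52), Stmn3 (−0.34) and Map1b (−0.64, and −0.32 over both its loci) fell. The list's median was −0.14 (adjusted p = 0.00646, and adjusted p = 0.311 with an estimated correlation). Of 32 synaptic vesicle genes 8 fell and 3 rose (Vamp2, Cplx2 and Bsn), 14 and 3 when adjusted over the list alone. Sv2c (−1.80), Cplx1 (−0.59) and Syt4 (−0.43) fell (list median −0.13, adjusted p = 0.000982, and adjusted p = 0.116 with an estimated correlation). Of 35 channel genes 8 fell and none rose, 8 and 3 when adjusted over the list alone. Kcnd2 (−0.93), Scn1a (−0.80) and Kcnab2 (−0.54) fell, and the list did not pass (adjusted p = 0.0948). Of 30 receptor genes Grin3a alone fell, and none when adjusted over the list alone (adjusted p = 0.749). Of 35 guidance genes Efnb3 rose, and Nrp1, Nrp2, Sema3e, Epha5 and Robo2 fell, 2 and 5 when adjusted over the list alone (adjusted p = 0.422).

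Of 22 cholesterol genes 6 fell, among them Fdps/Rusc1 (−0.65), Hmgcs1 (−0.36), Insig1 (−0.37) and Cpe/Msmo1 (−0.21), a locus that also holds the neuropeptide enzyme gene Cpe. When adjusted over the list alone 8 fell and 1 rose. The median was −0.26 (adjusted p = 0.000553, and adjusted p = 0.116 with an estimated correlation). Of 80 cytoplasmic ribosomal genes 8 rose and 4 fell (Rps27l, a paralog of Rps27, Rpl36a, Rpl37 and Rps2), 15 and 4 when adjusted over the list alone. Rps14 rose by 0.53 and Rpl26 by 0.35 (median 0.16, adjusted p = 0.000982, and adjusted p = 0.116 with an estimated correlation). Of 7 interferon and antigen presentation genes both that rose, B2m and H2-D1, encode parts of MHC class I. B2m rose from 21.5 ± 2.64 to 61.5 ± 0.916 FPKM and H2-D1 from 59.6 ± 0.742 to 92.6 ± 4.24 FPKM. When adjusted over the list alone 5 rose and none fell (median 0.56, adjusted p = 0.00539, and adjusted p = 0.168 with an estimated correlation).

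Nuclear-encoded oxidative phosphorylation did not pass as a list (adjusted p = 0.512). Of 75 members Ndufa3, Ndufa6, Ndufa7 and Ndufb7 rose, and Atp5b, Ndufa10 and Uqcrfs1 fell, 8 and 6 when adjusted over the list alone. The mitochondrial ribosome had Mrps28, Mrpl32, Mrpl34 and Mrpl9 up and none down of 78, 3 and 0 when adjusted over the list alone (adjusted p = 0.289). Mitochondrial fusion, fission and transport had Dnm1l, Gdap1 and Miga2 down and none up of 26, 4 and 2 when adjusted over the list alone (adjusted p = 0.574). Of 53 primary cilium genes Kif3c, a kinesin subunit, fell by 0.28, and none when adjusted over the list alone (adjusted p = 0.705). Of 9 motile cilium genes Rsph9, listed at 0 in control, was called higher, at 2.21 ± 0.783 FPKM (adjusted p = 0.512). Of 23 injury and stress genes the neuropeptide gene Adcyap1 fell by 0.97 (adjusted p = 0.574). Of 16 immediate early genes Egr1 (−0.57), Fos (−0.36) and Dusp1 (−0.35) fell, and 1 rose when adjusted over the list alone (adjusted p = 0.471). No cell cycle gene of 6 was called by limma (adjusted p = 0.574), and 1 (Ccne2) had an unadjusted p under 0.05. Of the 4 Dlk1-Dio3 genes Meg3 rose by 0.42, and Rian spread widely in control (1216 ± 1602 FPKM).

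The mitochondrial genome has 4 tested loci. The locus with 9 genes (mitochondrial positions 5328 to 14070) was at 2178 and 2238 FPKM in the control libraries, 8848 and 8921 in the miR-1247 libraries and 5869 and 5899 in E18. It rose by 2.01 ± 0.0233 with miR-1247 and by 1.41 ± 0.0233 at E18. The call with miR-1247 was lost under quantile normalization only. The mt-Nd1/mt-Nd2 locus was at 35797 and 12777 FPKM in control and 33062 and 61217 with miR-1247, and that difference did not pass (adjusted p = 0.215). It fell by 1.92 at E18, to 5669.5 ± 33.3 FPKM. Both controls listed mt-Cytb and mt-Nd6 at 0. The miR-1247 libraries gave 3691 and 3743 FPKM for mt-Cytb and 1297 and 1232 for mt-Nd6, which has the coordinates of the locus with 9 genes. Mitochondrial loci held 10.4% and 4.43% of all FPKM in control, 12.9% and 19.1% with miR-1247, and 4.24% and 4.28% at E18.

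Among the highest fold changes with miR-1247, Snrpe, a splicing protein, rose from 5.33 and 2.67 FPKM in the control libraries to 20.9 ± 0.981 FPKM (2.18 ± 0.362). Msi1, B9d1, Psg16 and Miip were at 0 in 1 or both control libraries at the named locus. The sums of their loci changed by 0.88, 1.02, 1.23 and 1.76, and the sum for B9d1 did not pass (adjusted p = 0.329). Single loci of Xkr4, Tppp and Usp47 were also called higher, and none of these passed when their loci were summed (0.34, 0.16 and 0.33). Among the lowest, Miat, a long noncoding RNA of neurons, fell from 61.4 ± 1.99 to 19.5 ± 1.20 FPKM (−1.60 ± 0.0675). Lrp1b (36.3 ± 19.5 to 7.56 ± 2.25 FPKM), Rps27l (−2.03), Sv2c (−1.80) and Rbm3 (−1.77), a cold-induced RNA binding protein, fell. Nme5 was at 7.42 ± 3.52 FPKM in control and at 0 in 1 miR-1247 library. Colgalt2 and Ank2 changed by −0.80 and −0.46 when their loci were summed. Arf6 fell by 3.30 at 1 locus and changed by −0.01 over both (adjusted p = 0.961).

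The third comparison asks how far miR-1247 RGCs were from E18. E18 RGCs had 4185 loci higher and 2919 lower than miR-1247 RGCs, 7104 in all, against 7108 for E18 and control. Under median ratio scaling 3468 were higher and 3510 lower. Cd24a (6.75 ± 0.191 to 781 ± 1.47 FPKM), Dcx, Tes, Rpl29 and Gpc2 were among the highest at E18, with log2 fold changes of 5.68 to 6.66. Rd3l (−7.33), Mgarp (−6.87), Rasgrf1 (−6.52) and Faim2 (−6.08) were among the lowest, as was Slc6a11, whose loci summed to −2.67. Slc17a6 did not pass (−0.05, adjusted p = 0.519). Thy1 was lower at E18 by 0.84 ± 0.0377, and Rbpms (2.44), Pou4f1 (2.60), Pou4f2 (1.97) and Gap43 (3.30) were higher. Of 22 RGC identity genes 15 were higher at E18 than with miR-1247 and 6 lower, the same when adjusted over the list alone (adjusted p = 0.0183, and adjusted p = 0.153 with an estimated correlation).

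Whether miR-1247 moved RGCs toward E18 levels was measured across loci. The fold changes of the 2 contrasts correlated weakly (r = 0.190, rho = 0.158, 10320 loci), with a covariance of 0.113. Shared controls alone gave a covariance of 0.0213 on average and at most 0.0297 in simulations with an unchanged miR-1247 group (r = 0.0765), and an r of 0.499 when no group changed. With 1 control library for each contrast, so that none was shared, r was 0.130 and 0.115. Of the 324 loci that rose with miR-1247, 179 were higher at E18, 94 lower and 51 not called. Of the 571 that fell, 255 were lower at E18, 197 higher and 119 not called. In total 434 moved toward E18 and 291 away, where independent calls would give 296 and 320, a comparison that leaves the shared controls out of account. These counts fell to 31 and 27 without miR-1247 library 1, 35 and 31 without miR-1247 library 2, 56 and 43 without control library 1, 43 and 30 without control library 2, and 118 and 71 or 118 and 70 without E18 library 1 or 2.

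Direct targets of a microRNA would be lower as a set. Of the tested loci 656 had a 7-base seed match in an annotated 3' UTR and 9340 had none. Their median log2 fold changes were −0.01 and −0.03, a difference of 0.02 (camera p = 0.954, and p = 0.943 with an estimated correlation). The means were −0.0354 and −0.0310, so that the differences of means and of medians have opposite signs. The median with sites lay at percentile 99.4 of 10000 random lists of like UTR length and level, whose medians centred on −0.05. Of loci with a match, 50 (7.62%) fell and 10 rose, and of those without 505 (5.41%) fell and 292 rose. For the 108 loci with 8-base matches the difference of medians was also 0.02, at percentile 85.0 of their random lists, and 2.78% of them fell, a smaller share than without a match. Higher or lower levels of seed-match loci as a set were not detectable with this test. A simulated drop of 0.2 at all seed-match loci was recovered by the same test (difference of medians −0.194). The observed difference of 0.02 therefore argues against a drop of that size over the set. Smaller drops, or drops at few targets, stay open.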

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

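Leaving out loci at 0, summing loci of a name, and leaving out mitochondrial loci were chosen after seeing the data. No list or named gene that passed its threshold changed direction under an alternative. The excess of higher loci turned under median ratio scaling, to 3442 higher and 3517 lower for E18 against control and 3468 and 3510 for E18 against miR-1247. Among list results 662 kept their side of the threshold, 8 gained it and 10 lost it. Among named genes 3719 kept it, 9 gained it and 614 lost it.

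The correlation of the developmental and miR-1247 fold changes (0.190) was 0.130 and 0.115 with 1 control library for each contrast, 0.198 with loci summed, 0.178 at FPKM of at least 5, 0.214 with a pseudocount of 0.1, 0.182 with quantile normalization, 0.204 with equal totals, 0.158 by rank, 0.159 without loci at 0 and 0.159 without mitochondrial loci. It ran from 0.175 to 0.228 with 1 library left out. Shared controls add a positive covariance, and 1 control library for each contrast removes it as far as the control libraries vary independently. Other causes of these differences were not tested.

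The 895 miR-1247 genes became 291 with no variance trend, 295 with only 4 libraries and 469 with replicate number as a block, although replicate numbers do not pair these samples. Loci toward E18 (434) became 156 with no variance trend, 241 with the block and 1303 at an unadjusted threshold, and loci away from it (291) became 90, 151 and 876. With 1 library left out the 3 counts ran from 63 (without miR-1247 library 1) to 223 (without E18 library 1), from 31 to 118 and from 27 to 71. Fewer libraries leave fewer degrees of freedom, and a group's lone library is then assumed to vary like the other groups. The cause of the drop with no variance trend was not tested. The developmental count ran from 6031 to 6927 and that of E18 against miR-1247 from 6005 to 7099.

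Of the lists past the threshold, 6 in the developmental and 6 in the miR-1247 contrast, the count was 1 and 1 with an estimated correlation, and 6 to 7 with 1 library left out. The cause was not tested. The median difference for seed-match loci stayed between 0.00761 and 0.0306 with 1 library left out. Without counts of reads the limits that depth sets could not be computed.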

Other observations

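All tests in this part were chosen after the results they measure were seen. Groups of 2 libraries are too small for a test on other splits of the samples.

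The mean over 22 RGC identity genes was 6.21 and 6.25 (log2) in control and 5.46 and 5.45 with miR-1247, a change of −0.78 (SE 0.0293). A lower share of RGCs that raises all other cell types alike is argued against by the rod mean minus the amacrine mean, which changed by −1.19 (SE 0.342, 95% interval −2.28 to −0.0982), though this rests on the rod genes Rom1 and Reep6, of which Reep6 did not pass. The values of all 4 amacrine, 5 Müller and astrocyte and 3 bipolar genes, Mbp, Col6a1 and Crybb3 lay above control, most without passing, so a lower share of RGCs together with a change in rods stays open, as does a higher share of amacrine cells (mean of their 4 markers changed by 0.46, SE 0.249, 95% interval −0.34 to 1.25). Pairing of the seed with each gene's 3' UTR has little support for the list as a set, since 2 of 17 genes that fell carry a match (Rbpms and Isl2). Matches were rare over all loci too (656 with and 9340 without), so the count does not show that the list has fewer matches than other loci. An effect of miR-1247-5p on RGC identity by other routes may remain and was not tested.

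Mitochondrial RNA was higher with miR-1247 at 3 of 4 loci. The other mitochondrial loci stood at 2178 FPKM or more in both control libraries, so the zeros of mt-Cytb and mt-Nd6 there may be failed estimates. The summed mitochondrial FPKM was 37976 and 15014.6 in control, 46898 and 75113 with miR-1247, and 15757 and 15963 at E18. Most of the sum in control came from the mt-Nd1/mt-Nd2 locus (35797 and 12777 FPKM), which spans mitochondrial positions 1 to 5016. Which transcripts within that span gave these values was not tested, so they cannot be assigned to the named genes alone. The log2 sum changed by 1.31 (SE 0.613, 95% interval −0.64 to 3.26) between control and miR-1247, so a rise of all mitochondrial RNA stays open, as the control libraries differ among themselves.

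The fold changes of miR-1247 followed the developmental ones weakly. Their covariance of 0.113 lay above the highest of 100 simulations with shared controls (0.0297), and without loci at 0 it was 0.0744 against 0.0180. Shared controls, as simulated from the spread between libraries of a group, and loci at 0 each fall short of the whole covariance. A deviation common to both control libraries would enter both contrasts and was not simulated, so shared controls as a cause are not excluded. A partial return toward an E18 program may be 1 reading, and a lower share of mature RGC transcripts from damage or mixture another. No test here separates them. The injury and stress list did not pass with miR-1247 (camera adjusted p = 0.574), with 1 of 23 genes lower and 0 higher. The lack of a list call does not exclude damage. Of the 17 RGC identity genes that fell with miR-1247, 12 were higher at E18 and 5 lower. At most of these genes the fall thus led away from E18. The 4 amacrine genes, above control with miR-1247 but most without passing, all fell at E18.

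Some genes outside every list were singled out after their values were seen. Igfbp4 rose with miR-1247 by 1.40, Igfbp2 by 0.95, Car2 by 0.84, Nptx2 by 0.73 and Pax6, which amacrine cells and RGCs both express, by 0.42. Chrna6 fell by 0.71 and Rgs4 fell by 0.85. Xist summed over its 2 loci was at 3.50 and 2.63 FPKM in control, 0 in both miR-1247 libraries and 42.6 and 37.9 at E18. Genes of the Y chromosome summed to 24.8 and 26.6, 26.9 and 22.2, and 33.1 and 33.5 FPKM.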
